A study of Sus scrofa with 15 samples.

How the data were processed

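Total RNA of pig granulosa cells at days 0, 1, 2, 4 and 7 of culture was measured on Affymetrix porcine genome arrays with biotin-labelled target, 3 arrays for each day and 15 in all, per the labels. The deposited values are log2 intensities, background-corrected, quantile-normalized and summarized per probe set by robust multi-array average (RMA), per the submitters' processing notes; the version of RMA is not given in the sources used here. The log2 scale was checked on the values, which ran from 2.29 to 14.9 with array medians of 6.40 to 6.55. The correlation of arrays of the same day was 0.963 to 0.996, and none of the 105 pairs of arrays was identical. Of 24123 probe sets, 124 controls were left out and used only as measures of array quality, which left 23999.

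Genes were named from the array annotation and a reference table of gene names. Of the tested probe sets, 10069 had 1 symbol (6765 symbols), 198 had several and 13732 had none. Probe sets with several symbols or none were counted but not named. COL1A1, RUNX2 and MKI67, chosen in advance, had no named probe set and are not reported. No genome build was used, so no positions are given. Where a gene had more than 1 probe set, that with the highest mean was used for gene lists.

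The day of culture was fitted as a factor to all 15 arrays with limma 3.58.1 in R 4.3.3 (linear model, moderated t test, empirical Bayes). Each later day was compared with day 0, and each day from day 2 on with the sampled day before it. A probe set was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 change was at least 1 in size. The time course was tested with the moderated F test over the 4 changes from day 0, with the same limits applied to the range of day means. Changes were called early and kept when called on day 1 and in the same direction on day 7, early and returning when called on day 1 and in the opposite direction between days 1 and 7, and late when called on day 7 against both day 0 and day 1 but not past the adjusted p on day 1. The fit was tested on simulated data, with independent noise for each array and the same spread of a probe set on all days. On day 1 against day 0, 0% (0 of 67) of added changes of 0.75 were recovered, 86.6% of 1.5 and 98.5% of 3. There were 4 false calls among 23799 unchanged probe sets. On day 7 against day 4 the shares recovered were 1.49%, 77.6% and 97.0%, with 2 false calls. A change of 0.75 lies under the minimum change of 1, which lowers its recovery. Recovery by the adjusted p alone was not simulated, so the part due to each limit is not known.

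The test used 44 gene lists, written down before the data were examined, with 570 measured members (540 genes, 30 of them in more than 1 list). They cover granulosa identity, steroidogenesis, cholesterol synthesis, luteinization, growth factor and signaling pathways, cell division, matrix, adhesion, cytoskeleton, mesenchymal lineages, stress, metabolism and markers of other cell types. Each was tested with camera at a preset correlation of 0.01 and adjusted over lists within a comparison; camera with an estimated correlation and fry were run beside it. A count adjusted over the list alone used only the members' p values.

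The genes named in the text were set by a rule, also written before the data were examined. It takes the 10 largest rises and falls on day 1 and on day 7 against day 0 and the 5 largest of each in the other comparisons, among called genes whose groups do not overlap. It adds up to 4 members of each list with the largest change on day 7, and 16 genes fixed by name. Members of a group that were not the largest are left out of the text to keep it short.

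Whether replicate numbers pair the arrays was checked from the correlation of deviations from the day means. It was above 0.1 for every pair in 6 comparisons and not in day 1 against day 0, where it ran from 0.0609 to 0.333. Only arrays with the same number were compared, and the deviations within a day sum to 0. A departure of replicate 1 alike on every day would thus give positive values for the other replicates too, so the check cannot show that their numbers pair arrays. Since nothing in the labels says that replicate numbers pair arrays, the main results use no block, and values with replicate number as a block are given where they change a list call or change a count by over 1.5 times. For named genes the closing section gives the number of calls the block changed.

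Alternatives tried were a second quantile normalization, arrays shifted to the same median, cyclic loess, leaving out the dimmest 40% of probe sets, eBayes with trend and robust settings, array weights, replicate number as a block, no minimum change, a treat test against 0.5, only the 6 arrays compared, the mean of all probe sets of a gene, and leaving out each array in turn. The use of replicates 2 and 3 only, and the fit without day 4 replicate 2, were chosen after seeing the data. The estimation of array weights stopped before it converged.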

Results

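Transcript levels were measured on Affymetrix porcine genome arrays in granulosa cells, the hormone-producing cells that line the ovarian follicle, on days 0, 1, 2, 4 and 7 of culture. Each of the 5 days had 3 arrays, 15 in all, and the number of arrays limits the precision of every value. The labels call the replicates biological, but nothing says whether they came from separate animals or separate cultures, so p values measure the spread between these arrays, whether biological or technical. Per the labels, the cells lose their differentiated state over this time and those of day 7 are called DFOG cells. The array held 23999 probe sets after 124 control probe sets were left out. Of these, 10069 carried 1 gene symbol, and 13732 had no gene in the annotation used, so that many changed probe sets could be counted but not named. Values are log2, and changes are log2 changes with their standard error (SE) from limma, with 3 arrays on each day. The lower quartile of the arrays was 4.41 to 4.68, and a change from or to a level in or below that range is read as a lower bound, so that the order of such genes is uncertain in every comparison.

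Over the time course HSD17B1, which makes estradiol from estrone, went from a mean of 13.52 ± 0.25 (SD, n = 3) on day 0 to 9.41 on day 1 and 5.63 ± 0.42 on day 7. INHA, the inhibin alpha subunit, went from 14.26 ± 0.20 to 7.05 ± 0.20. In the other direction, ACTA2, the smooth muscle actin, went from 7.68 ± 0.61 to 14.23 ± 0.03, and COL15A1, a collagen of basement membrane zones, went from 4.40 ± 0.57 to 12.66 ± 0.07. The limma F test called 5670 probe sets (23.6% of those tested), of which 1990 had day means at least 2 apart. On the first principal component, with 50.3% of the variance, the arrays lay at -107 to -103 on day 0, -25.3 to -13.3 on day 1, 15.6 to 21.5 on day 2, and 43.1 to 58.5 on days 4 and 7. The third, with 13.1%, held the replicate 1 array of every day at 29.4 to 48.1 and the other 10 arrays at -41.4 to -5.78. Day 4 replicate 2 differed from the other arrays in its control probe sets, with an actin 3′ minus 5′ difference of 2.12, against 0.02 to 1.68 on the others.

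**Figure D1:**
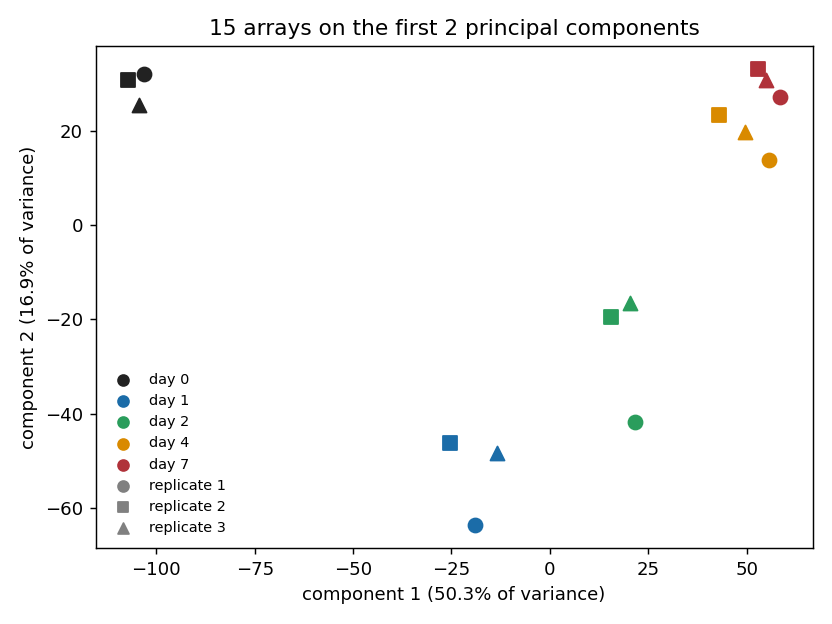
Each point is 1 of the 15 arrays, placed on the first and second principal components of all tested probe sets (unitless scores), with color for day and shape for replicate. The arrays of day 0 lie at -107 to -103 on the first component and those of days 4 and 7 at 43.1 to 58.5.

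The first day in culture was compared with freshly isolated cells to see how early the change began. RGS5, a regulator of G protein signaling found in pericytes, rose by 6.19 ± 0.71 (72.8-fold), and FHL2, a LIM-domain partner of actin-linked transcription, rose by 6.04 ± 0.20. PMEPA1, a feedback inhibitor of TGF-beta signaling, rose by 5.69 ± 0.41, and SGK1, a serum-induced kinase, by 5.39 ± 0.27. The adhesion proteins THBS1 and LAMB1 rose by 5.02 ± 0.38 and 4.94 ± 0.23. Rises of 4.87 to 5.31 were also found for KHDRBS3, an RNA-binding protein, S100A10, an annexin partner, HMGA1, a chromatin protein, and DAB2, an endocytic adaptor. Among the falls, NEBL, an actin-binding protein of the nebulin family, changed by -4.37 ± 0.26, and HSD17B1 by -4.11 ± 0.33. The replication genes PCLAF and RRM2 changed by -4.08 ± 0.36 and -3.71 ± 0.39. The glycosyltransferase B3GNT3 changed by -4.11 ± 0.27, SFTPC, known as a lung surfactant protein, by -3.91 ± 0.22. The fatty acid ligase ACSL6 changed by -3.84 ± 0.47, and RNASE1, MFSD4A and MAL2 by -3.62 to -3.54.

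Genes of cell division fell together on day 1. Of 16 measured mitosis genes, 15 fell and 0 rose, and 16 fell when adjusted over the list alone (median -1.87, camera adjusted p = 1.23e-10, and adjusted p = 0.373 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, changed by -2.58 ± 0.31 and the mitotic kinase AURKB by -2.34 ± 0.25. Of 12 genes of DNA replication, 8 fell, also when adjusted over the list alone (median -1.44, adjusted p = 5.55e-07, and adjusted p = 0.311 with an estimated correlation). PCNA, the sliding clamp of the polymerases, changed by -2.10 ± 0.21.

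Of 14 genes of integrins and focal adhesion 8 rose on day 1, also when adjusted over the list alone (median 1.41, adjusted p = 1.79e-05, and adjusted p = 0.0204 with an estimated correlation). Among them were the actin cross-linker ACTN1 at 4.57 ± 0.14 and the caveolar protein CAV1 at 4.43 ± 0.43. Of 22 actin cytoskeleton genes 11 rose, and 12 when adjusted over the list alone (median 1.07, adjusted p = 3.76e-08, and adjusted p = 0.153 with an estimated correlation). TAGLN, an actin-binding protein of smooth muscle, rose by 4.35 ± 0.23. The matrix list had 4 risen and 1 fallen of 19 genes, 6 and 1 when adjusted over the list alone, without a call for the list (median 0.54, adjusted p = 0.360).

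Of 21 granulosa identity genes, 9 fell and 1 rose on day 1, the same counts as adjusted over the list alone (median -0.25, adjusted p = 0.00568, and adjusted p = 0.0669 with an estimated correlation). The follistatin gene FST changed by -2.16 ± 0.21 and AMH, the anti-Müllerian hormone, by -2.18 ± 0.27, while INHA at -1.31 ± 0.35 was no longer called without day 1 replicate 3 (-1.04). Of 16 steroidogenesis genes 6 fell and 2 rose, with the same counts adjusted over the list alone (median -0.82, adjusted p = 2.92e-04, and adjusted p = 0.0534 with an estimated correlation). FDXR, which passes electrons to the mitochondrial steroid enzymes, changed by -2.80 ± 0.20, and HSD3B1, which makes progesterone, by 1.89 ± 0.43. The side-chain cleavage enzyme CYP11A1 at 2.31 ± 0.71 was not called without day 1 replicate 1 (1.36), day 0 replicate 1 (2.13) or day 0 replicate 2 (2.08). Of 11 cholesterol synthesis genes 5 fell and 1 rose, also when adjusted over the list alone (median -0.92, adjusted p = 4.24e-04, and adjusted p = 0.556 with an estimated correlation). INSIG1, the sterol sensor that retains SREBP, changed by -2.50 ± 0.37.

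In all, 3001 probe sets passed the test on day 1 (12.5%), 1553 higher and 1448 lower, and 761 of them changed at least 4-fold. Which direction was more frequent depended on the processing: 51.7% were higher as reported, 47.1% after a second quantile normalization and 45.7% after cyclic loess. Without day 0 replicate 1 or day 1 replicate 1 the share was 46.4% or 49.8%. The 3 values of each day did not overlap for 37.0% of probe sets, where chance gives 10%. The 3′ minus 5′ difference of actin, a measure of transcript integrity, was 0.97 to 1.68 on day 0 and 0.18 to 1.01 on day 1, so it moved with every gene group above. That of dap, a control transcript added to the RNA, was 1.72 to 1.77 on day 0 and 1.47 to 1.63 on day 1. Those of the added controls thr and phe overlapped between the days. Since dap does not come from the cells, a difference in processing between these days cannot be told apart from one in the cells' RNA.

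On day 2, the comparison with day 0 gives the cumulative change. FHL2 rose by 6.97 ± 0.20, and RGS5 by 6.88 ± 0.71. FN1, the fibronectin gene, rose by 6.73 ± 0.36, LAMB1 by 6.58 ± 0.23 and PMEPA1 by 6.46 ± 0.41. ACSL6 changed by -6.27 ± 0.47, HSD17B1 by -6.24 ± 0.33, and DAPL1 by -5.85 ± 0.89. MAL2, a protein of apical membrane traffic, changed by -5.49 ± 0.29 and SELENBP1, a selenium-binding protein, by -4.97 ± 0.47. All 16 mitosis genes fell, also when adjusted over the list alone (median -2.88, adjusted p = 9.14e-15, and adjusted p = 0.163 with an estimated correlation). Of 19 matrix genes 11 rose, also when adjusted over the list alone (median 1.59, adjusted p = 2.59e-04, and adjusted p = 0.0723 with an estimated correlation). Of 14 integrin and focal adhesion genes 11 rose, again with the same count over the list alone (median 1.58, adjusted p = 7.78e-08, and adjusted p = 0.00439 with an estimated correlation). Granulosa identity had 7 genes lower and 2 higher of 21, also adjusted over the list alone (median -0.21, adjusted p = 0.00485, and adjusted p = 0.0606 with an estimated correlation). Of all probe sets, 3306 passed the test, 1844 higher and 1462 lower; 37.3% did not overlap between the days, where chance gives 10%. The actin 3′ minus 5′ difference, 0.97 to 1.68 on day 0 and 0.02 to 0.68 on day 2, moved with these groups.

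On day 4 large rises from day 0 were those of FN1 (7.96 ± 0.36), FHL2 (7.85 ± 0.20), TAGLN (7.52 ± 0.23), COL15A1 (7.44 ± 0.49) and LAMB1 (7.22 ± 0.23). Those of FHL2, COL15A1 and LAMB1 are lower bounds, since their day 0 means were 4.09, 4.40 and 4.21. Large falls were those of GSTA1, a glutathione transferase abundant in steroid-making cells (-7.90 ± 0.53), HSD17B1 (-7.63 ± 0.33), DAPL1 (-7.43 ± 0.89), ACSL6 (-6.26 ± 0.47) and INHA (-6.19 ± 0.35). Of 22 actin cytoskeleton genes 18 rose, also when adjusted over the list alone (median 2.53, adjusted p = 3.30e-15, and adjusted p = 0.0181 with an estimated correlation). Likewise 15 of 19 matrix genes rose, again with the same count over the list alone (median 2.78, adjusted p = 1.72e-06, and adjusted p = 0.0181 with an estimated correlation). Of 21 granulosa identity genes 8 fell and 0 rose, and of 16 steroidogenesis genes 8 fell and 2 rose, the same counts as adjusted over the list alone (adjusted p = 1.37e-04 and 1.05e-04, and adjusted p = 0.0181 for each with an estimated correlation). Mitosis genes were lower in 7 of 16 cases, also adjusted over the list alone (median -0.93, adjusted p = 8.50e-05, and adjusted p = 0.432 with an estimated correlation). DNA replication was lower in 0 of 12, over all genes and over the list alone (median -0.11, adjusted p = 0.541). In total 3811 probe sets passed the test, 2229 higher and 1582 lower, and 42.4% did not overlap between the days, where chance gives 10%. The actin 3′ minus 5′ difference on day 4 was 0.07, 2.12 and 0.63 in replicates 1, 2 and 3, against 0.97 to 1.68 on day 0. That of the added control dap was 1.01, 3.52 and 1.29, against 1.72 to 1.77 on day 0.

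The end point of the culture was compared with the freshly isolated cells to describe the dedifferentiated state. COL15A1 rose by 8.26 ± 0.49 (SE, 3 arrays on each day), FHL2 by 7.97 ± 0.20, FN1 by 7.91 ± 0.36 and TAGLN by 7.69 ± 0.23. CCL2, a chemokine that attracts monocytes, rose by 7.47 ± 0.58 and the small proteoglycan DCN by 7.22 ± 0.73. LAMB1 rose by 7.06 ± 0.23, the collagen cross-linking enzyme LOX by 7.05 ± 0.58. CNN1, the smooth muscle calponin, rose by 6.79 ± 0.25 and the adhesion molecule VCAM1 by 6.61 ± 0.57. Among the falls, GSTA1 changed by -8.31 ± 0.53, HSD17B1 by -7.89 ± 0.33, DAPL1 by -7.74 ± 0.89, INHA by -7.21 ± 0.35, and ACSL6 by -6.22 ± 0.47. LHCGR, the receptor for luteinizing hormone, changed by -6.15 ± 0.34. MAL2, FST, SELENBP1 and IGFBP2, a binding protein of insulin-like growth factors, changed by -6.01 to -5.05. On day 0, COL15A1, FHL2, DCN, LAMB1, CNN1 and VCAM1 had means of 4.09 to 4.63, near the lower quartile of those arrays (4.59 to 4.68), so their rises are lower bounds and their order is uncertain.

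Of 21 granulosa identity genes 9 fell and 0 rose on day 7, also when adjusted over the list alone (median -0.90, adjusted p = 2.05e-05, and adjusted p = 0.00914 with an estimated correlation). NR5A2, a nuclear receptor that drives granulosa steroid genes, changed by -4.79 ± 0.33 and AMH by -2.46 ± 0.27. FOXL2, the transcription factor of granulosa fate, differed by 0.04 ± 0.14 (adjusted p = 0.873), and FSHR, the receptor for follicle-stimulating hormone, by -0.90 ± 0.42 (adjusted p = 0.124), neither past the test. Of 16 steroidogenesis genes 7 fell and 3 rose, also adjusted over the list alone (median -0.95, adjusted p = 4.34e-04, and adjusted p = 0.0264 with an estimated correlation). FDXR changed by -4.39 ± 0.20, whereas HSD3B1 and CYP11A1, enzymes that lead from cholesterol to progesterone, rose by 5.38 ± 0.43 and 3.03 ± 0.71. STAR, which brings cholesterol into mitochondria, differed by -0.96 ± 0.28 and NR5A1, a master regulator of steroid genes, by -0.95 ± 0.18, both under the minimum change. CYP19A1, the aromatase gene, differed by -0.18 ± 0.19 (adjusted p = 0.530); its probe set could also read the near-identical pig paralogs, so the value is uncertain. Luteinization and cumulus expansion had 5 lower and 2 higher of 13 genes, also adjusted over the list alone (median -0.70, adjusted p = 0.0359, and adjusted p = 0.0975 with an estimated correlation). PTGES, a prostaglandin E synthase, changed by -3.31 ± 0.26 and PTX3, a pentraxin of the cumulus matrix, by 2.47 ± 0.32.

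The matrix and cytoskeleton lists rose. Of 22 actin cytoskeleton genes 19 rose (median 2.76, adjusted p = 4.30e-16, and adjusted p = 0.0187 with an estimated correlation), among them ACTA2 at 6.55 ± 0.32. Of 19 matrix genes 16 rose (median 3.11, adjusted p = 6.31e-08, and adjusted p = 0.0130 with an estimated correlation), with LUM, a proteoglycan of collagen fibrils, at 5.95 ± 0.70. Of 14 integrin and focal adhesion genes 12 rose (median 2.30, adjusted p = 3.13e-08, and adjusted p = 0.00326 with an estimated correlation), with the integrin subunits ITGB3 and ITGA5 at 5.54 ± 0.26 and 4.84 ± 0.26. Of 14 matrix protease and inhibitor genes 10 rose (median 1.41, adjusted p = 0.00245, and adjusted p = 0.0975 with an estimated correlation), with MMP1, the interstitial collagenase, at 4.58 ± 0.97 and TIMP1, its inhibitor, at 3.28 ± 0.16. No member of these 4 lists fell, and every count was the same when adjusted over the list alone. Basement membrane genes went both ways, 3 up and 2 down of 6, over all genes and over the list alone (median 1.90, adjusted p = 0.273), with LAMB2 at -2.51 ± 0.28.

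Of 8 mesenchymal transition genes 4 rose on day 7, also adjusted over the list alone (median 1.26, adjusted p = 0.0274, and adjusted p = 0.0975 with an estimated correlation), among them the cadherin CDH11 at 6.06 ± 0.30 and S100A4 at 4.69 ± 0.49, while VIM, the intermediate filament vimentin, differed by 0.42 ± 0.14, under the minimum change. Of 7 smooth muscle and pericyte markers 5 rose, also adjusted over the list alone (median 3.28, adjusted p = 0.00634, and adjusted p = 0.0975 with an estimated correlation), with ACTG2, a smooth muscle actin, at 5.72 ± 0.46 and SMTN, smoothelin, at 3.28 ± 0.30. Of 9 theca and stromal markers 4 rose and 1 fell, also over the list alone (median 0.39, adjusted p = 0.273); DCN, LUM and ACTA2 are also in other lists, and INSL3, made by theca cells, changed by -2.36 ± 0.23. Macrophage markers had 1 higher and 1 lower of 15 (median -0.17, adjusted p = 0.345), and lymphocyte and granulocyte markers 0 of 13 past the test (median -0.02, adjusted p = 0.708). Endothelial markers had 2 higher and 1 lower of 12, with a negative median and test direction and a positive mean (-0.07 and 0.15, adjusted p = 0.837): PECAM1 and ERG rose by 1.49 ± 0.21 and 3.43 ± 0.36, and TIE1 changed by -2.40 ± 0.22. Red blood cell markers had 0 of 3 past the test (median -0.31, adjusted p = 0.318). The counts of these 4 other cell types were the same when adjusted over the list alone. Oocyte markers had 2 lower of 7, also over the list alone (median -0.50, adjusted p = 0.0468, and adjusted p = 0.349 with an estimated correlation). The call was lost without day 0 replicate 1 (median -0.28, adjusted p = 0.182) or day 7 replicate 3 (adjusted p = 0.0580), with arrays shifted to the same median (adjusted p = 0.0582) and without the dimmest 40% of probe sets (median -2.08, adjusted p = 0.0626).

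Whether the day 7 cells carried marks of other mesenchymal lineages was read from further lists, whose counts were the same when adjusted over the list alone except where given. Surface markers of mesenchymal stromal cells had 4 higher of 10 genes (median 0.62, adjusted p = 0.0654). This list was called without the dimmest 40% of probe sets (median 1.61, adjusted p = 0.0159), without day 0 replicate 2 (adjusted p = 0.0394) or without day 7 replicate 2 (adjusted p = 0.0409). Its members include PDGFRB, a receptor for platelet-derived growth factor, at 4.62 ± 0.36 and THY1 at 4.08 ± 0.24. Osteogenic genes had 3 higher and 1 lower of 12 (median 0.53, adjusted p = 0.299), with SPP1, osteopontin, at 6.35 ± 0.69 and the bone transcription factor DLX5 at 4.70 ± 0.62. Chondrogenic genes had 2 higher of 8 (median 0.14, adjusted p = 0.470), with SOX9 at 2.39 ± 0.19. Adipogenic genes had 2 higher and 3 lower of 15, and 3 and 3 over the list alone (median -0.13, adjusted p = 0.449), with the fatty acid carrier FABP4 at 2.69 ± 0.38 and PPARG at -4.21 ± 0.57. Myogenic genes had 1 higher and 1 lower of 11, with a positive median and mean and a negative test direction (0.02 and 0.06, adjusted p = 0.877). Pluripotency genes had 1 higher and 1 lower of 7 (median -0.43, adjusted p = 0.643), and POU5F1 differed by -0.20 ± 0.15, not past the test. Epithelial junction and keratin genes had 2 higher and 1 lower of 14, with a negative median and test direction and a positive mean (-0.06 and 0.51, adjusted p = 0.980); KRT19 rose by 3.46 ± 0.55 and the desmosomal protein DSP by 3.17 ± 0.34.

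Mitosis genes were lower than on day 0, 8 of 16 and none higher, also when adjusted over the list alone (median -1.05, adjusted p = 2.05e-05, and adjusted p = 0.480 with an estimated correlation), with TOP2A at -2.14 ± 0.31. DNA replication genes had 0 of 12 past the test, over all genes and over the list alone (median -0.43, adjusted p = 0.154). In all, 3993 probe sets passed the test on day 7 (16.6%), 2246 higher and 1747 lower, and 1405 changed at least 4-fold. The 3 values of each day did not overlap for 46.5% of probe sets, where chance gives 10%. The actin 3′ minus 5′ difference was 0.97 to 1.68 on day 0 and 0.19 to 0.59 on day 7, and so it moved with the groups named here. That of the added control dap was 1.72 to 1.77 on day 0 and 1.25 to 1.45 on day 7, while those of thr and phe overlapped. A difference in processing between these days thus cannot be told apart from one in the cells' RNA.

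**Figure D2:**
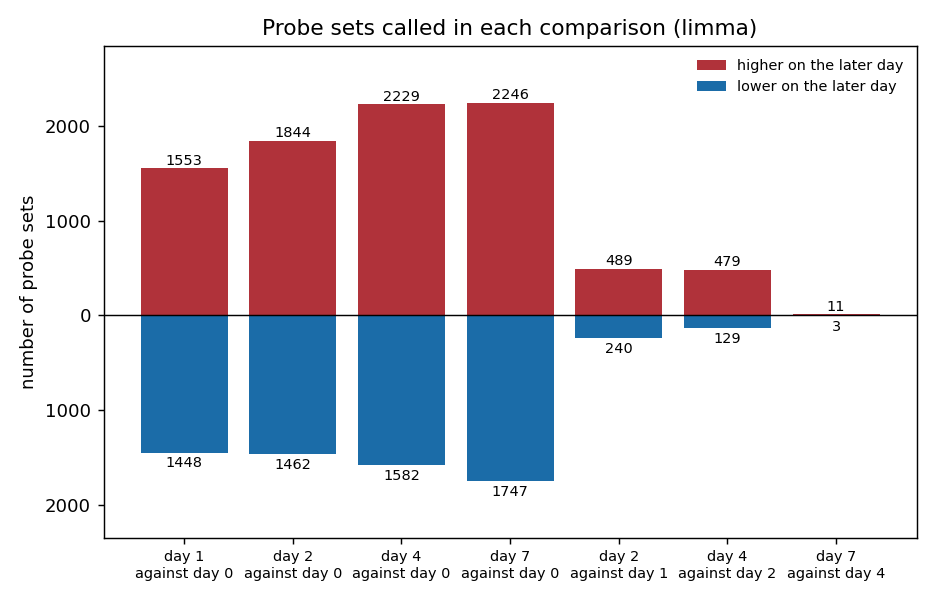
Bars give the number of probe sets called by limma in each comparison, higher on the later day above 0 and lower below it. Against day 0 the counts were 3001, 3306, 3811 and 3993 on days 1, 2, 4 and 7, and the last step, day 7 against day 4, had 14.

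**Figure D3:**
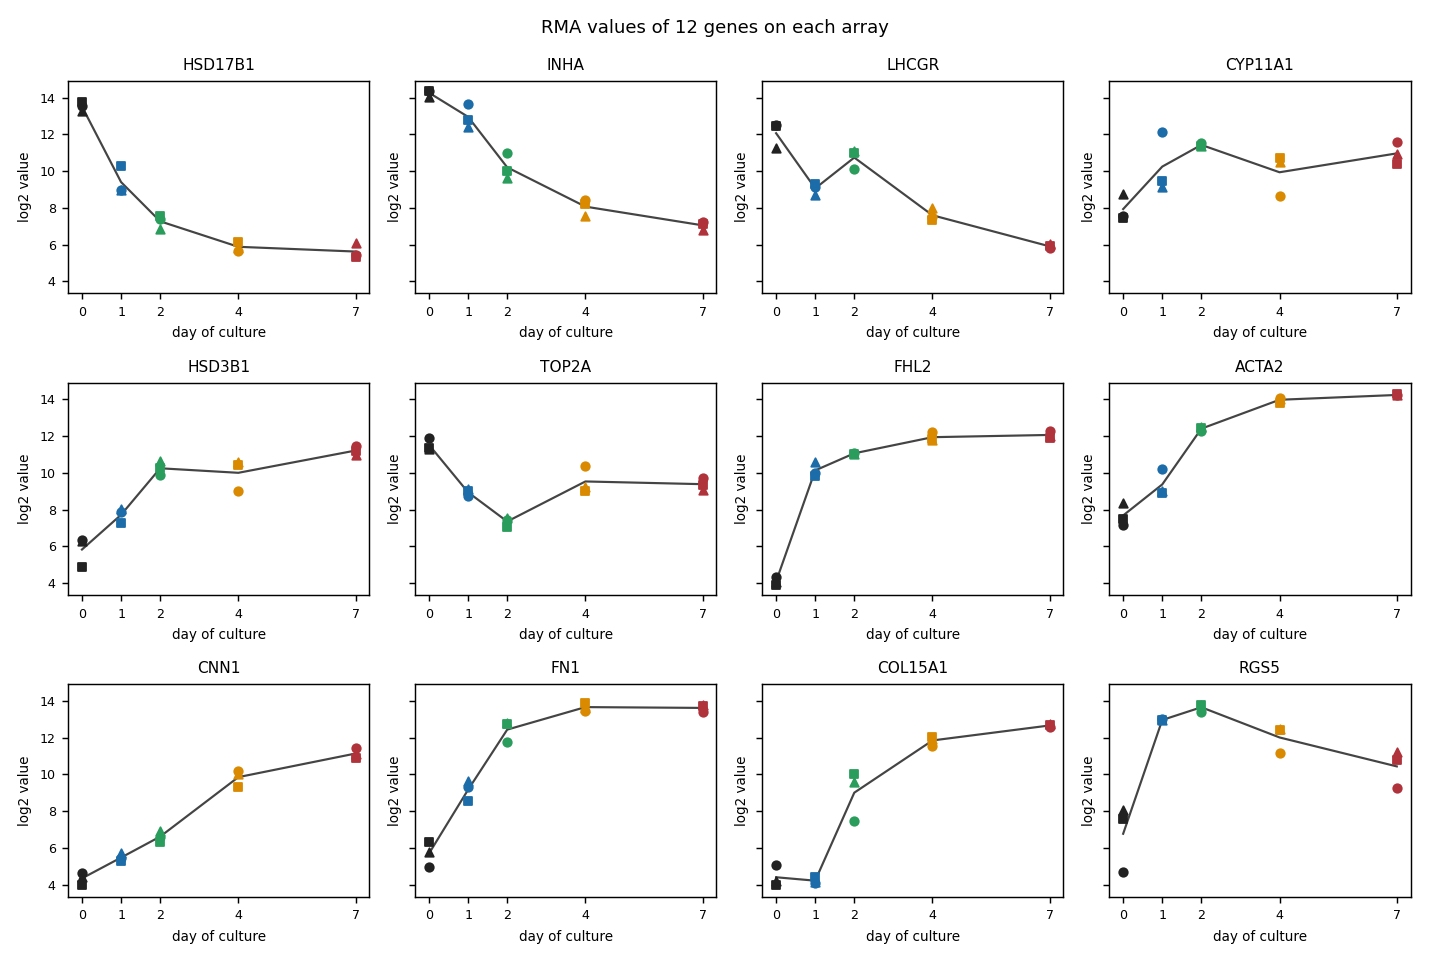
Points are the log2 RMA values of 12 genes on each of the 15 arrays (circle, square and triangle for replicates 1, 2 and 3) against day of culture, and lines join the day means. HSD17B1, INHA and LHCGR ended far below their day 0 level, and FHL2, ACTA2, CNN1, FN1 and COL15A1 far above it.

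Between days 1 and 2, COL15A1 rose by 4.79 ± 0.49, a lower bound since its day 1 mean was 4.22. TRH, a prohormone, rose by 4.62 ± 0.56 and EPCAM, an epithelial adhesion molecule, by 4.28 ± 0.42. NID2, a nidogen of basement membranes, rose by 4.18 ± 0.48 and the keratin KRT19 by 4.07 ± 0.55. The ion channel protein CLIC2 changed by -4.03 ± 0.59, GSTA1 by -3.22 ± 0.53, MOBP by -2.95 ± 0.15 and INHA by -2.74 ± 0.35. Of 6 basement membrane genes 3 rose, also over the list alone (median 1.10, adjusted p = 8.29e-04, and adjusted p = 0.214 with an estimated correlation). ABCB1, a drug efflux pump, changed by -2.44 ± 0.60 and was not called without day 1 replicate 1 (-2.24), day 1 replicate 2 (-2.40), day 2 replicate 2 (-2.15) or day 2 replicate 3 (-1.91), and the mean of its probe sets changed by -0.97, not past the test. Of 19 matrix genes 7 rose, and 10 when adjusted over the list alone (median 1.10, adjusted p = 2.32e-07, and adjusted p = 0.0510 with an estimated correlation), with FN1 at 3.27 ± 0.36. Of 16 genes of the unfolded protein response 6 rose, also over the list alone (median 0.90, adjusted p = 1.28e-07, and adjusted p = 0.0558 with an estimated correlation). Part of this was a return: on day 1 against day 0 the same list had 3 higher and 3 lower, also over the list alone, and was called lower (median -0.59, adjusted p = 0.0451, and adjusted p = 0.562 with an estimated correlation). That call was lost without day 0 replicate 1 or day 1 replicate 2 (adjusted p = 0.0999 and 0.0918), with arrays shifted to the same median (0.0578) or with the mean of probe sets (0.103), and on day 2 against day 0 the median was 0.43 (adjusted p = 0.176). SDF2L1, a chaperone of the endoplasmic reticulum, rose from day 1 to day 2 by 2.32 ± 0.19. Glycolysis and hypoxia had 6 higher of 16, and 6 higher and 1 lower adjusted over the list alone (median 0.33, adjusted p = 5.29e-04, and adjusted p = 0.255 with an estimated correlation), with the lactate dehydrogenase LDHA at 1.49 ± 0.23.

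LHCGR rose by 1.68 ± 0.34 from day 1 to day 2, a call lost without day 2 replicate 2 (1.54) or day 2 replicate 3 (1.49), and on day 2 it was still below day 0 (-1.32 ± 0.34, and -0.78 and not called with array weights). FSHR rose by 2.55 ± 0.42. Mitosis genes fell further, 8 of 16, and 10 when adjusted over the list alone (median -1.03, adjusted p = 1.28e-07, and adjusted p = 0.424 with an estimated correlation), with TOP2A at -1.58 ± 0.31, while RRM2 rose by 2.18 ± 0.39. In this step 729 probe sets passed the test, 489 higher and 240 lower, and 21.0% did not overlap between the days, where chance gives 10%. Fewer were called without day 1 replicate 2 (478), day 2 replicate 2 (465) or day 2 replicate 3 (451).

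Between days 2 and 4, most genes of the mitosis list rose again. Of 16 mitosis genes 14 rose, and 15 when adjusted over the list alone (median 1.84, adjusted p = 1.28e-22, and adjusted p = 0.0581 with an estimated correlation). Of 12 DNA replication genes 6 rose, also over the list alone (median 1.11, adjusted p = 5.05e-12, and adjusted p = 0.0581 with an estimated correlation). TOP2A rose by 2.18 ± 0.31, RRM2 by 2.49 ± 0.39 and PCLAF by 2.94 ± 0.36. ENPP1, an ectoenzyme that makes pyrophosphate, rose by 3.51 ± 0.31, CNN1 by 3.23 ± 0.25, MGP, an inhibitor of calcification, by 2.96 ± 0.50, and the glutamate transporter SLC1A1 by 2.96 ± 0.37, although the mean of its 5 probe sets changed by 0.91. GSTA1 changed by -3.61 ± 0.53, EPCAM by -3.46 ± 0.42, LHCGR by -3.14 ± 0.34, JAKMIP1 by -2.69 ± 0.24 and SLC6A4, the serotonin transporter, by -2.47 ± 0.42.

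Of 22 actin cytoskeleton genes 11 rose from day 2 to day 4, also over the list alone (median 0.98, adjusted p = 8.89e-17, and adjusted p = 0.0237 with an estimated correlation), with TAGLN at 1.90 ± 0.23 and ACTA2 at 1.57 ± 0.32. Of 21 granulosa identity genes 4 fell, and 6 when adjusted over the list alone (median -0.60, adjusted p = 7.29e-05, and adjusted p = 0.0237 with an estimated correlation), with INHA at -2.14 ± 0.35 and FST at -1.89 ± 0.21. Smooth muscle and pericyte markers had 3 higher of 7, also over the list alone (median 0.90, adjusted p = 0.00397, and adjusted p = 0.0712 with an estimated correlation). Surface markers of mesenchymal stromal cells had 2 higher of 10, and 3 over the list alone (median 0.65, adjusted p = 0.00397, and adjusted p = 0.0581 with an estimated correlation), with THY1 at 2.74 ± 0.24. In this step 608 probe sets passed the test, 479 higher and 129 lower, and 17.5% did not overlap between the days, where chance gives 10%.

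**Figure D4:**
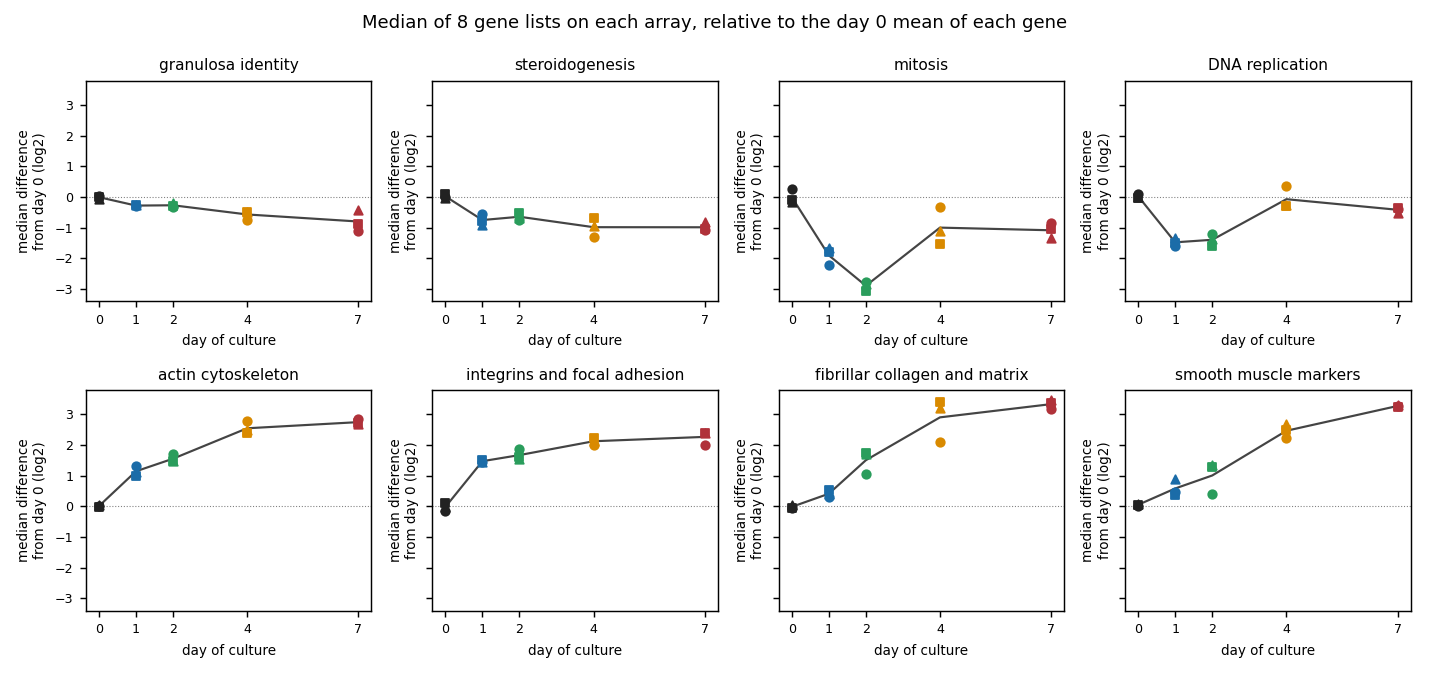
Points give, for each array, the median over the genes of 8 lists of the log2 difference from each gene's day 0 mean, against day of culture (circle, square and triangle for replicates 1, 2 and 3), and lines join the day means. Mitosis and DNA replication fell to days 1 and 2 and rose again by day 4, while the actin, adhesion, matrix and smooth muscle lists rose to day 7.

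Between days 4 and 7 few transcripts passed the test. On simulated data it recovered 77.6% of changes of 1.5 and 1.49% of changes of 0.75. The simulated noise was independent between arrays and equally wide on every day. Among the real arrays, day 4 held the lowest correlation of arrays of the same day (0.963), so recovery there may be lower. The minimum change of 1 lowers the share for changes of 0.75, and recovery without that limit was not simulated. That share thus does not measure the sensitivity of the adjusted p alone to smaller changes. Without a minimum change 15 probe sets passed in place of 14, and smaller changes are not excluded. C1S, a complement protease, rose by 1.88 ± 0.24 (adjusted p = 0.0108). A2M, a protease inhibitor, rose by 1.76 ± 0.23, but not without day 4 replicate 2 (1.69), and LOXL4, a matrix cross-linking enzyme, rose by 1.51 ± 0.22, but not without day 4 replicate 1, 2 or 3 or day 7 replicate 2 (adjusted p = 0.0778, 0.102, 0.0731 and 0.0644). The mean of all probe sets of A2M and of LOXL4 changed by 0.66 and 0.59, not past the test. TNNT1, a troponin, rose by 1.75 ± 0.27, a call that ended without any 1 of the 6 arrays (1.49, 1.89 and 1.87 without day 4 replicates 1, 2 and 3; 1.78, 1.61 and 1.85 without those of day 7). The protease inhibitor SPINK5 changed by -1.65 ± 0.26, a call that ended without day 4 replicate 2 or 3 (-1.31 and -1.75) or day 7 replicate 1, 2 or 3 (-1.55, -1.69 and -1.70).

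No list member passed the test over all genes between days 4 and 7. Camera called 11 lists, and all 11 calls were lost with an estimated correlation and by fry. The matrix list was called by camera with 2 members higher of 19 adjusted over the list alone (median 0.29, adjusted p = 3.11e-04, and adjusted p = 0.138 with an estimated correlation), and so was the actin list with 2 of 22 (median 0.24, adjusted p = 1.05e-04, and adjusted p = 0.268 with an estimated correlation). Smooth muscle and pericyte markers had 3 higher of 7 over the list alone (median 0.82, adjusted p = 0.00632, and adjusted p = 0.15 with an estimated correlation). Cholesterol synthesis, with 0 of 11 over the list alone (median 0.34, adjusted p = 1.05e-04, and adjusted p = 0.268 with an estimated correlation), lost its call without day 4 replicate 1 (adjusted p = 0.0779). Granulosa identity, with 0 of 21 over the list alone (median -0.14, adjusted p = 0.0112, and adjusted p = 0.138 with an estimated correlation), lost its call without day 7 replicate 2 (adjusted p = 0.0553).

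Other lists called by camera in this step were lost in the same way. BMP and activin genes had 0 of 16 past the test over the list alone (median -0.19, adjusted p = 0.00739, and adjusted p = 0.15 with an estimated correlation). Luteinization had 1 lower of 13 (median -0.08, adjusted p = 0.0120, and adjusted p = 0.138 with an estimated correlation), with no call without day 7 replicate 3 (adjusted p = 0.0611). DNA replication had 0 of 12 (median -0.30, adjusted p = 0.00739, and adjusted p = 0.539 with an estimated correlation), with no call without day 4 replicate 1 or day 7 replicate 3 (adjusted p = 0.886 and 0.0931). Interferon response had 1 higher of 18 (median 0.24, adjusted p = 0.00114, and adjusted p = 0.268 with an estimated correlation), with no call without the same arrays (adjusted p = 0.0779 and 0.0690). TGF-beta had 0 of 8 (median -0.21, adjusted p = 0.0253, and adjusted p = 0.268 with an estimated correlation), with no call without day 4 replicate 1 or 2 or day 7 replicate 3 (adjusted p = 0.0577, 0.0717 and 0.0690). Inflammatory genes had 0 of 19 (median 0.09, adjusted p = 0.0330, and adjusted p = 0.459 with an estimated correlation), with no call without day 4 replicate 2 or 3 or day 7 replicate 1 (adjusted p = 0.101, 0.0902 and 0.749), or with replicate number as a block (adjusted p = 0.0528).

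In this step 14 probe sets passed the test, 11 higher and 3 lower, of which 8 had a clear gene name, and 10.6% did not overlap between the days, where chance gives 10%. With replicate number as a block 41 passed; without day 4 replicate 2 the count was 4 and without day 7 replicate 2 it was 9.

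When changes arose was read from the calls of day 1 and day 7. FHL2, LAMB1, TAGLN, HSD17B1 and ACSL6 were among 1938 probe sets, 985 up and 953 down, that were called on day 1 and in the same direction on day 7, which is 64.6% of the day 1 calls. A group of 428 (14.3%) was called on day 1 and then in the opposite direction between days 1 and 7, which need not be a full return to day 0. From day 1 to day 7, RRM2 rose by 4.59 and PCLAF by 3.42, and CLIC2 changed by -5.38. RGS5, which reached a mean of 13.65 on day 2, changed by -2.52 but was still called higher on day 7 than on day 0. It is therefore also early and kept, so these classes overlap. Late changes numbered 851, 611 up and 240 down, with no call on day 1, and held COL15A1, DCN, LUM, ACTG2, THY1, GSTA1 and PPARG, the adipocyte regulator. With replicate number as a block, ACTG2, GSTA1 and PPARG were called on day 1 as well (1.31, -1.07 and -1.57), so their place among the late changes depends on the block. In 20 simulations without change, each of the 3 classes held 0 probe sets by limma. Almost nothing is called in such data, so this result was fixed in advance and does not test the classes. Independent calls on days 1 and 7 would share 145 probe sets up and 105 down. The 2 comparisons use the same day 0 arrays, so they are not independent.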

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

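The tests of day 4 replicate 2 in this part were chosen after the result was seen. The 18S ribosomal RNA control, one of 124 control probe sets outside the comparisons, read 11.87 on day 4 replicate 2, where the highest of the other 14 arrays read 8.34. The gap exceeded 2 on the log2 scale. It was the only such result among the controls. Groups of 3 arrays are too small for a test of outlying samples, so none was made.

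Day 4 replicate 2 also had the highest 3′ minus 5′ differences of 5 of the 5 transcripts dap, thr, phe, actin and GAPDH. The difference of dap, a control transcript added to the RNA, was 3.52 (others 1.01 to 1.77), which argues against breakdown of the cells' RNA before the controls were added as the sole cause. Shorter copies made in reactions after that addition stay a candidate explanation, since all 5 were highest. No biological explanation was tested. Without this array the last step, day 7 against day 4, had 4 probe sets called in place of 14.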

How the results depend on the processing

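The alternatives with replicates 2 and 3 only, and without day 4 replicate 2 in every fit, were chosen after seeing the data. Of 180 counts under alternatives 153 stayed within 1.5 times the reported value and 27 moved. Among values of named genes, 96.4% of 20090 stayed on the same side of the threshold, 424 were weaker, 300 stronger and 0 reversed by limma. Direction was compared only where a call was made, so values not called in either fit count as unchanged whatever their sign. Among values of lists, 92.6% of 3675 stayed on the same side by the same rule, 141 were weaker, 125 stronger and 5 reversed.

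Without a minimum change, as its construction implies, counts against day 0 grew to 6020, 6248, 7360 and 7514 on days 1, 2, 4 and 7. Day 2 against day 1 had 1461, day 4 against day 2 had 1002, and the time course had 8605. The timing classes held 3936 (early and kept), 1411 (early and returning) and 1756 (late). The treat test against 0.5, which is stricter by construction, gave 210 for day 2 against day 1, 256 for day 4 against day 2, 3 for day 7 against day 4 and 213 early and returning.

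Array weights, estimated without convergence, gave 1349 for day 2 against day 1 and 144 for day 7 against day 4; with replicates 2 and 3 only these were 1321 and 55. The share of called probe sets that were higher fell under 50% with array weights on day 1 against day 0 (47.0%) and day 7 against day 4 (48.6%), and with replicates 2 and 3 only on days 1 and 2 against day 0 (45.1% and 49.2%). The cause was not tested. Leaving out the dimmest 40% of probe sets gave 4 for day 7 against day 4. With only the 6 arrays compared, fewer arrays estimate the spread, and day 4 against day 2 had 371 and day 7 against day 4 had 0 by limma. There 1240 probe sets had an unadjusted p under 0.05, against 1111 with all 15 arrays in the fit, where chance gives 1199.95.

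With replicate number as a block, where replicates are taken to pair, counts were 3225, 3513, 3996 and 4197 against day 0, and 966, 778 and 41 for the 3 later steps; every reported call was shared, none in the opposite direction. The block ended the list calls of cholesterol synthesis on day 2 against day 0 (adjusted p = 0.0522), of heat shock and luteinization on day 4 against day 2 (0.0596 and 0.0720) and of inflammatory genes on day 7 against day 4 (0.0528). Among values of named genes it ended 0 calls and made 40 by limma. It made list calls of Wnt on day 2 against day 1 (0.0376) and of BMP and activin on day 4 against day 0 (0.0449).

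Leaving out each array in turn, counts ran from 2761 to 3071, 3160 to 3364, 3651 to 3917 and 3787 to 4136 on days 1, 2, 4 and 7 against day 0. They ran from 451 to 986 for day 2 against day 1, 419 to 653 for day 4 against day 2 and 4 to 14 for day 7 against day 4. The first of these was lowest without day 2 replicate 3 and the last without day 4 replicate 2. The time course ran from 5320 to 5907.

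The test fry gave the opposite direction for basement membrane on day 1 (median -0.47) and for pluripotency on days 1, 2 and 7 (-0.19, -0.29 and -0.43), all against day 0, and the cause was not tested. Mitosis on day 7 against day 4 was not called by camera in the reported fit (adjusted p = 0.205), and had medians of -0.40 to 0.28 when arrays were left out. Camera called it lower without day 4 replicate 2 or 3 (adjusted p = 1.07e-05 and 0.037) or day 7 replicate 1 (0.0092). Without day 4 replicate 1 the sign was reversed and it was called higher (0.049). The cause was not tested. Of the 78 list calls made by camera in the 7 comparisons, 63 were lost with an estimated correlation and 13 by fry. Fry made 75 others in the direction of camera and the 4 named above in the opposite direction. Signal near background limits small changes of dim probe sets, which were kept in the reported results.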

Other observations

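The tests of cell mixture and of replicate 1 in this part were chosen after the result was seen, and those of other splits before the data were examined. On day 7 against day 0, signaling genes went both ways, with counts that were the same when adjusted over the list alone. TGFB1 rose by 4.57 ± 0.35, while TGFBR3, a co-receptor, changed by -2.29 ± 0.50 (TGF-beta list: 2 higher and 1 lower of 8, median 0.29, adjusted p = 0.577). The BMP and activin list had 6 higher and 2 lower of 16 (median 0.83, adjusted p = 0.158), with ACVR1 at 2.36 ± 0.17 and ID2 at -3.12 ± 0.42. Wnt genes had 2 higher and 1 lower of 9 (median 0.54, adjusted p = 0.299), with SFRP1 at 4.37 ± 0.83. Notch genes had 2 higher and 2 lower of 6, with a positive median and a negative mean and test direction (0.07 and -0.03, adjusted p = 0.841). YAP and TEAD targets had 4 higher of 7 (median 1.32, adjusted p = 0.0196, and adjusted p = 0.371 with an estimated correlation), with F3, tissue factor, at 5.06 ± 0.34. Immediate early genes had 5 higher and 5 lower of 14 (median -0.28, adjusted p = 0.708), with MYC at 3.11 ± 0.18 and FOS at -4.73 ± 0.38. Inflammatory genes had 5 higher and 1 lower of 19 (median 0.38, adjusted p = 0.273), with LIF at 5.15 ± 0.35, and interferon response genes 2 and 1 of 18 (median 0.13, adjusted p = 0.708). The IGF system had 2 higher and 2 lower of 9, with a negative median and a positive mean (-0.22 and 0.05, adjusted p = 0.604); IGFBP6 rose by 2.35 ± 0.40 and IGF1 changed by -1.27 ± 0.25.

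Metabolic and stress genes on day 7 against day 0 also had the same counts when adjusted over the list alone. Glycolysis and hypoxia had 5 higher of 16 (median 0.47, adjusted p = 0.0552; called without day 0 replicate 2 or day 7 replicate 2, adjusted p = 0.0395 and 0.0427), with the glucose transporter SLC2A1 at 2.99 ± 0.25, whereas oxidative phosphorylation had 0 of 18 past the test (median -0.01, adjusted p = 0.645) and ribosomal proteins 0 of 21 (median 0.24, adjusted p = 0.0886, and 0.0375 without day 0 replicate 2). The unfolded protein response had 3 higher of 16 (median 0.53, adjusted p = 0.147), with SDF2L1 at 2.73 ± 0.19, and heat shock 3 of 15 (median 0.31, adjusted p = 0.317), with HSPB8 at 3.24 ± 0.27. Oxidative stress defense had 4 higher and 6 lower of 20 (median -0.04, adjusted p = 0.449), with GPX1 at 2.85 ± 0.22 and GCLC at -2.74 ± 0.22. Lysosome and autophagy had 3 higher and 1 lower of 18 (median 0.53, adjusted p = 0.0918), with NPC2 at 2.69 ± 0.34, although the mean of its probe sets changed by 0.84, under the minimum change. Cell cycle arrest and p53 targets had 2 higher and 4 lower of 14 (median -0.43, adjusted p = 0.382), with CDKN1A at 2.08 ± 0.46 and GADD45G at -2.78 ± 0.35. Cholesterol synthesis had 1 higher of 11, with a positive median and mean and a negative test direction (0.05 and 0.09, adjusted p = 0.841). Reference genes had 2 higher of 11 (median 0.66, adjusted p = 0.0496, and adjusted p = 0.349 with an estimated correlation), a call lost without day 0 replicate 1 or 3 (adjusted p = 0.0559 and 0.0656) or day 7 replicate 1, 2 or 3 (adjusted p = 0.0648, 0.0521 and 0.0580). It was also lost with arrays shifted to the same median (adjusted p = 0.0589) and without the dimmest 40% of probe sets (adjusted p = 0.110). ACTB differed by 0.93 ± 0.17, under the minimum change.

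Granulosa identity members fell while actin, matrix and smooth muscle genes rose. If granulosa cells had only been diluted, genes made by them alone and above background would have fallen alike. The day 2 changes of the 9 members that fell by day 7 spanned 6.32, from -6.24 for HSD17B1 to 0.07 for AMHR2. For members that meet those conditions, this argues against a lower share of cells with an unchanged profile. Whether each member meets them was not tested. The day 7 against day 1 changes of the 33 members that rose by at least 2 on day 7 spanned 9.08. They ran from -2.52 ± 0.71 for RGS5 to 6.55 ± 0.73 for DCN. A lower share that raised every other cell type alike, and outgrowth of 1 cell type with a fixed profile, both predict equal changes. They do so only for members above background and not made by granulosa cells. Which members these are was not tested, so the range argues against both for such members only and excludes neither. Outgrowth of a cell type that itself changed in culture stays open and may account for part of the rise.

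Replicate 1 stood apart from replicates 2 and 3 on every day. The hybridization control bioB was lowest on the replicate 1 array on 4 of 5 days (8.16 to 9.06, others 8.53 to 9.27), so by bioB a difference in hybridization or scanning and a difference in the cells or cultures of replicate 1 cannot be told apart. The control dap, added to the RNA, was lowest on the replicate 1 array on 5 of 5 days and read 7.53 to 9.0 on replicate 1 and 8.97 to 10.1 on the others. Although dap does not come from the cells, its normalized level is read relative to the cells' own transcripts. It thus cannot tell a difference in handling from one in the cells or cultures. A difference in the cells, alone or beside one in handling, stays open. With replicates 2 and 3 only, 3376 probe sets were called on day 1 and 4281 on day 7 against day 0, sharing 2670 of 3001 and 3692 of 3993 calls, none in the opposite direction.

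Other splits of the arrays were counted for each number of called probe sets. For each of the 7 comparisons of 2 days, 1 of 10 splits, the real one, gave as many as reported (3001, 3306, 3811 and 3993 against day 0, and 729, 608 and 14 for later steps), and 10 splits are too few for a share under 0.05. The highest other count was 0 by limma in 6 of them, and 1 for day 7 against day 4, in a split that followed replicate 1. For the time course the real grouping alone, 1 of 100, gave as many as 5670; the highest other, 3156, kept all 3 day 0 arrays in 1 group. For early and kept 1 of 100 did (1938, highest other 0), and for late 1 of 100 (851, highest other 1). The median of the other groupings was 0 for each of these counts. Groups that mix days far apart have a wide spread and few calls, so the real grouping was favored and chance cannot be excluded in this way. For early and returning 3 of 100 groupings gave as many as 428. The highest other was 2139, with the 3 day 0 arrays put in the group of day 1, while the next, 726, had 0 of them there. Day 0 stood far from the rest on the first principal component, but whether this gave the larger count was not tested.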
